A study of Mus musculus with 48 samples.

How the data were processed

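Values were used as deposited: log2 signals of 45101 probe sets on 48 Affymetrix mouse arrays, made with RMA per the submitters' processing notes, which give no version. RMA includes background correction, quantile normalization and summarization on the log2 scale, but the spread of values differed by title week, and the notes do not say whether all arrays were normalized together. No value column was left unused. Skin RNA was labelled with biotin by an in vitro transcription kit per the labels.

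Groups came from the titles, which name treatment, route or agent, week and replicate, and from the treatment labels. The array titled PBS ip week 5 replicate 1 carries the treatment label IL15 and was placed in no group. It was tried as its title says and as its treatment label says. Titles give weeks 5 and 6, where the labels of the weeks of treatment say 5/6. The labels do not tie an agent to a route. From what is known of the study, PBS ip was the control for il15rb, PBS pump for jak3i and PBS gavage for jak12i, and PBS of the other route and PBS of all routes were tried as alternatives. Replicate numbers gave no pairing: with group means removed, arrays of equal number correlated between -0.492 and 0.236 within the comparisons between groups, so no comparison was paired, and a replicate block was an alternative. The p-values measure the spread between arrays, which the series calls biological replicates, and separate animals are not stated beyond that.

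Probe sets naming 1 gene symbol numbered 34958, while 932 named several and 9211 none. Symbols were updated through the Entrez identifier for 34754. Each of 18194 genes was represented by its probe set of highest mean over the 47 arrays, and 9012 genes had more than 1. Genes above the table's median of 6.70 in at least 3 arrays were kept, 13650 in all. Of 156 called gene results with several probe sets, 23 had both signs, none with the opposite one 0.5 or more from 0. Some probe sets lay near 0.

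Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over the 47 arrays with empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. Of 29 gene lists written by hand, 25 with at least 4 tested members were tested by camera with an inter-gene correlation of 0.01, adjusted over the 25, and again with an estimated correlation and by fry. Some members are shared: the regulatory T cell and checkpoint lists share Ctla4, and Cd274 is also in the interferon gamma response list. No list's mean, median and camera direction differed in sign where it passed. Lists that passed and 6 lead lists (T cell, cytotoxic lymphocyte, interferon gamma response, MHC class I, MHC class II and hair shaft) were carried through the alternatives in 7 comparisons, those of the treatments with PBS and of PBS ip with sham, a restriction made after a first run. Lists of the other 7 comparisons were not. Clock and glucocorticoid lists were compared by exact permutation tests, two-sided.

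Groups, comparisons, gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 16 panel genes in each comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 4 members of smallest p in each list that passed or led. The panel genes Il2rg and Dsg4 were not analysed here, and 1 other panel gene is not reported here. Chosen after seeing the data were the hair shaft covariate, leaving out 3 arrays with the skeletal muscle list below 8 (PBS gavage week 6 replicate 5, PBS ip week 13 replicate 3 and PBS pump week 13 replicate 2), leaving out 3 arrays of weeks 5 and 6 with the hair shaft list above 9 (sham replicate 4 and jak12i replicates 2 and 3), and the wider list of genes at an unadjusted p under 0.01 in PBS ip against sham.

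Simulated data with the real group sizes and gene spread tested the procedure. Over the 8 comparisons between groups, 1.5-fold changes were found for 58.3% to 78.0% of genes, 2-fold for 86.2% to 97.0% and 4-fold for 95.8% to 100%, and 3.37% to 7.45% of calls were false. Of 100 unshifted lists, at most 1 passed camera. The test cannot show false calls among correlated genes or lists, or groups of unequal spread. It was written after the alternatives were first run.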

Results

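Skin RNA of C3H/HeJ mice was measured on 48 Affymetrix expression arrays in a series on preventing alopecia areata by blocking the interleukin-15 (IL-15) pathway. In this mouse model the disease is known to follow grafting of skin from affected animals, and T cells attack the growing hair follicle. By their titles 12 arrays belonged to week 5, 18 to week 6 and 18 to week 13. The treatment names in the titles are il15rb, known of the study as an antibody that blocks the IL-15 receptor beta chain, jak3i, known as the Janus kinase (JAK) inhibitor tofacitinib, and jak12i, known as the JAK1 and JAK2 inhibitor ruxolitinib. Vehicle controls received phosphate-buffered saline (PBS) by intraperitoneal injection (ip), by pump or by gavage.

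Of the 48 arrays, 47 were placed in 13 groups. Week 5 held sham (n = 4), PBS ip (n = 4) and il15rb (n = 3). Week 6 held jak3i (n = 5), jak12i (n = 5), PBS pump (n = 3) and PBS gavage (n = 5). Week 13 held il15rb, jak3i, jak12i, PBS ip, PBS pump and PBS gavage with n = 3 each. One further week 5 array had a title naming PBS and a treatment label naming IL15, and it stayed in no group. The number of arrays limits the precision of every value.

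Values were log2 signals, 13650 genes were tested, and every adjusted p is from limma. Changes are given in log2 units ± the standard error (SE), and group values as mean ± SD. For a gene named as having risen or fallen, the arrays of both groups did not overlap unless overlap is stated. Where the lower group's mean lay below the highest 25th percentile of that week's arrays, near background, the change is a lower bound and a fold is given as at least the measured one. Ifng in all week 13 comparisons, Ifit1 under jak3i at week 6, and the averages of Ubd and Gzma over treatments are such cases too. Arrays of 1 group correlated between 0.973 and 0.996. The spread of values within an array differed by title week: the 75th percentile lay between 8.47 and 8.68 at week 5, between 8.15 and 8.35 at week 6, and between 8.68 and 8.78 at week 13. Week 5, week 6 and week 13 arrays therefore also differ as batches would. Every treatment comparison was made within 1 title week, but spread could differ between groups of a week too. At week 6 the 75th percentile lay between 8.22 and 8.25 in jak12i arrays and between 8.29 and 8.35 in PBS gavage arrays. The plot of genes higher and lower per comparison gives the counts side by side.

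**Figure D1:**
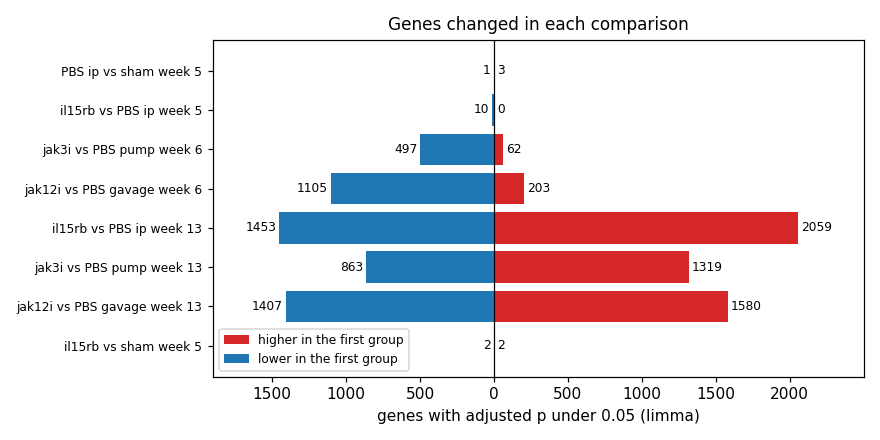
Number of genes higher and lower at an adjusted p under 0.05 (limma) in each of 8 comparisons between groups. The 3 week 13 comparisons had 3512, 2182 and 2987 genes, and the week 5 comparison of PBS ip with sham had 4.

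The week 5 comparison of PBS ip with sham asks what the skin of vehicle-treated mice expressed early, relative to sham animals. Interferon-induced genes tended to be higher in PBS ip skin, but with wide spread between arrays. Genes that respond to interferon gamma, such as the GTPases Iigp1, Irgm1 and Igtp that act against intracellular microbes, stood higher as a list, though not with an estimated correlation between genes. The gene with the clearest rise, Per2, belongs to the circadian clock. Limma called 3 genes higher and 1 lower (n = 4 and 4), against 684 genes at an unadjusted p under 0.05. Per2 rose by 1.78 ± 0.30 (3.42-fold, adjusted p = 0.00854), from 6.02 ± 0.21 in sham to 7.79 ± 0.11. Sectm1b rose by 0.86 ± 0.17 (adjusted p = 0.0421), Sectm1a rose by 0.72 ± 0.14 (adjusted p = 0.0421) and Leo1 fell by 0.41 ± 0.07 (adjusted p = 0.0145). Groups did not overlap for 573 genes, 4.20% of those tested, where chance gives 2.86%. The count of 4 became 1, 0 and 0 without PBS ip replicates 2, 4 and 5, and 2, 1, 0 and 2 without sham replicates 1, 2, 3 and 4. With quantile normalization between arrays no gene passed.

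Among genes that did not pass in PBS ip against sham, the coreceptor gene Cd8a of cytotoxic T cells differed by 0.40 ± 0.17 (adjusted p = 0.867) and the T cell attracting chemokine Cxcl9 by 0.79 ± 0.64 (adjusted p = 1). Iigp1 differed by 1.97 ± 0.64 (adjusted p = 0.583) and the antiviral gene Ifit1 by 1.44 ± 0.41 (adjusted p = 0.458). In camera, the interferon gamma response list was higher by a mean of 0.74 (adjusted p = 2.34e-10), with 18 of 18 members positive and none called over all genes, 4 adjusted over the list alone, and adjusted p = 0.221 with an estimated correlation. Without PBS ip replicate 2 the mean was 0.434. The type I interferon list was higher by 0.61 (adjusted p = 9e-18), with 8 members called adjusted over the list alone and adjusted p = 0.213 with an estimated correlation. MHC class I presentation, the display of antigen to CD8 T cells, was higher by 0.34 (adjusted p = 2.34e-10), with 3 members adjusted over the list alone and adjusted p = 0.213 with an estimated correlation. The cytotoxic lymphocyte list was higher by 0.24 (adjusted p = 0.00126) and adjusted p = 0.6 with an estimated correlation. It no longer passed without PBS ip replicate 3, at 0.152, or with the array of conflicting labels placed as its title says, at 0.0992. The common gamma chain and JAK-STAT list was higher by 0.14 (adjusted p = 0.00126) and adjusted p = 0.213 with an estimated correlation. Hair shaft genes were lower by 0.81 on the log2 scale in the mean (adjusted p = 0.00019), with adjusted p = 0.6 with an estimated correlation. That value depended on sham replicate 4, without which the mean change was 0.0801. Dermal matrix genes were lower with a mean of -0.24 (adjusted p = 0.00888) and adjusted p = 0.6 with an estimated correlation, and at -0.02 without the same sham replicate 4 they no longer passed.

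The week 5 comparison of il15rb with PBS ip asks what early blockade of the IL-15 receptor beta chain changed in the skin. Of the 10 genes that fell, 5 belong to the cytotoxic and T cell lists: Nkg7 and Ctsw of cytotoxic granules, the receptor gene Klrd1 of natural killer cells, and the CD3 chain genes Cd3g and Cd247 of the T cell receptor complex. Interferon-induced genes were lower as lists. Limma called no gene higher and 10 lower (n = 3 and 4), against 549 genes at an unadjusted p under 0.05. Arrays of both groups did not overlap for 1075 genes, 7.88%, where chance gives 5.71%. The count of 10 became 1, 0 and 3 without il15rb replicates 1, 2 and 3, and 2 and 3 without PBS ip replicates 3 and 5. It was 1 with the array of conflicting labels placed as its title says and 24 as its treatment label says.

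Nkg7 fell by 1.36 ± 0.27 under il15rb at week 5, 2.57-fold lower (adjusted p = 0.0217; 7.40 ± 0.03 against 8.77 ± 0.21), and Cd3g fell by 1.30 ± 0.24 (adjusted p = 0.0145). Cd247 changed by -0.83 ± 0.13 (adjusted p = 0.00465) and the death ligand gene Tnfsf10 by -1.10 ± 0.18 (adjusted p = 0.00465). Ddx60, an interferon-induced helicase gene, changed by -1.83 ± 0.36 (3.55-fold lower, adjusted p = 0.0217). The homing receptor gene Cxcr6 changed by -1.56 ± 0.32 (adjusted p = 0.0277). Klrd1, Ctsw, the gamma delta T cell receptor gene Trgv4 and Cd7 changed by -1.31, -1.01, -0.99 and -0.74 (each adjusted p = 0.0217). Cd8a did not pass at 0.07 ± 0.19 (adjusted p = 1), nor did Gzmb at -0.08 ± 0.38 (adjusted p = 1), Prf1 at -0.70 ± 0.19 (adjusted p = 0.237) or Cxcl9 at -2.40 ± 0.69 (adjusted p = 0.327). The target's own gene Il2rb did not pass at -0.35 ± 0.14 (adjusted p = 0.93).

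By camera the cytotoxic lymphocyte list was lower at week 5 under il15rb with a mean of -0.55 (adjusted p = 3.05e-13), with 3 of 14 members called over all genes and 6 adjusted over the list alone. The T cell list had a mean of -0.41 (adjusted p = 1.7e-10), with 2 of 11 called and 5 adjusted over the list alone. For the interferon gamma response the mean was -1.22 (adjusted p = 1.25e-22) and for the type I interferon response -0.82 (adjusted p = 2.6e-27), each with 0 members called over all genes and 12 adjusted over the list alone. With an estimated correlation these 4 lists kept adjusted p = 0.026, 0.0128, 0.0199 and 0.0199. MHC class I had a mean of -0.39 (adjusted p = 5.93e-12; 4 members adjusted over the list alone) and adjusted p = 0.0644 with an estimated correlation. The macrophage list had -0.62 (adjusted p = 1.72e-12; 2 adjusted over the list alone) and adjusted p = 0.0701 with an estimated correlation. MHC class II had -0.14 and the common gamma chain list -0.11 (adjusted p = 0.0238 and 0.0171), with adjusted p = 0.52 and 0.299 with an estimated correlation. Without PBS ip replicate 5 the latter no longer passed at -0.07. Cell cycle genes had -0.19 (adjusted p = 0.0397) and adjusted p = 0.726 with an estimated correlation, and without il15rb replicate 1 the mean change was 0.119. Dermal matrix genes had -0.32 (adjusted p = 0.000454) and adjusted p = 0.412 with an estimated correlation.

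The week 5 comparison of il15rb with sham asks how far skin under the antibody lay from skin of sham animals. Per2 was again the largest rise, and Gzmc, which encodes a granzyme of cytotoxic cells, was the largest fall. By camera 8 lists passed, all lower than sham and among them T cell and macrophage genes, but none passed with an estimated correlation. Limma called 2 genes higher and 2 lower (n = 3 and 4), against 1586 at an unadjusted p under 0.05. Per2 rose by 1.69 ± 0.32 (3.23-fold, adjusted p = 0.0256) and Sh3d21 by 0.93 ± 0.17 (adjusted p = 0.0256). Gzmc fell by 2.296 ± 0.45, at least 4.91-fold (adjusted p = 0.0335; 4.84 ± 0.32 against 7.14 ± 0.77), and Leo1 by 0.45 ± 0.08 (adjusted p = 0.023). Cd8a differed by 0.47 ± 0.19 (adjusted p = 0.31) and Cxcl9 by -1.61 ± 0.69 (adjusted p = 0.356). Camera placed the T cell list at -0.28 (adjusted p = 0.00266), the cytotoxic list at -0.31 (adjusted p = 0.00385), the macrophage list at -0.47 (adjusted p = 0.000428) and the dermal matrix list at -0.56 (adjusted p = 1.36e-05). With an estimated correlation these lists had adjusted p = 0.769, 0.895, 0.895 and 0.769. Members adjusted over the list alone numbered 4, 6, 2 and 4. In the dermal matrix list sham replicate 4 stood at 11.95, above the other sham arrays at 10.91 to 11.14.

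Groups of il15rb and sham did not overlap for 1795 genes, 13.2%, where chance gives 5.71%. The count of 4 became 0, 0 and 47 without il15rb replicates 1, 2 and 3, and 28 and 1 without sham replicates 3 and 4. The share called higher was 50% as deposited, 60% after quantile normalization and 66.7% after subtracting array medians.

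The week 6 comparison of jak3i with PBS pump asks what the inhibitor given as jak3i changed early. Interferon-induced antiviral genes fell, among them Ddx60, the 2'-5' oligoadenylate synthetase-like gene Oasl2 and Ifit1. Macrophage genes fell with them, including the complement genes C1qb and C1qc and the monocyte chemokine receptor Ccr2. Genes of MHC class II, which present antigen to CD4 T cells, also fell. The few rises were small and included Il1rn, which encodes the interleukin-1 receptor antagonist. Limma called 62 genes higher and 497 lower (n = 5 and 3). The share called higher was 11.1% as deposited and 31.5% after quantile normalization. Arrays of both groups did not overlap for 1246 genes, 9.13%, where chance gives 3.57%. The count of 559 became 364 without jak3i replicate 4, and 895, 165 and 203 without PBS pump replicates 1, 2 and 3. Against PBS gavage in place of PBS pump 6246 genes were called, and the labels do not tie jak3i to either route.

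Ddx60 fell by 2.37 ± 0.34 under jak3i at week 6, at least 5.16-fold (adjusted p = 9.76e-05; 5.23 ± 0.14 against 7.60 ± 0.39). Oasl2 fell by 2.14 ± 0.38, at least 4.41-fold (adjusted p = 0.000515), and Ifit1, Ifi44l and Rtp4 changed by -2.09, -2.13 and -2.03 (adjusted p = 0.0022, 0.000239 and 0.000311). The lectin gene Cd209e changed by -2.31 ± 0.43 (adjusted p = 0.000755), the monocyte chemokine gene Ccl8 by -2.25 ± 0.35 (adjusted p = 0.000145) and Ly86 by -2.06 ± 0.31 (adjusted p = 0.000143). C1qc changed by -1.66 ± 0.30 (adjusted p = 0.000617) and Ccr2 by -1.80 ± 0.35 (adjusted p = 0.00146). Cd3g changed by -1.57 ± 0.23 (adjusted p = 9.76e-05) and Ctsw by -0.95 ± 0.19 (adjusted p = 0.00185). H2-Ab1 and its chaperone Cd74 changed by -0.72 and -0.83 (adjusted p = 0.000303 and 0.000311), and the class I genes H2-D1 and H2-K1 by -0.51 and -0.76 (adjusted p = 0.00154 and 0.00182). Il1rn rose by 0.79 ± 0.20 (adjusted p = 0.0158) and Glt28d2 by 0.66 ± 0.11 (adjusted p = 0.000303). Cd8a, Cxcl9 and Il2rb did not pass at -0.09 ± 0.18, -1.57 ± 0.66 and -0.34 ± 0.13 (adjusted p = 0.902, 0.205 and 0.153).

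By camera 7 lists differed under jak3i at week 6, and none of the 7 kept an adjusted p under 0.05 with an estimated correlation. The type I interferon list had a mean of -1.02 (adjusted p = 4.66e-17; 10 of 19 members fell over all genes, 15 adjusted over the list alone) and adjusted p = 0.0963 with an estimated correlation. The macrophage list had -1.08 (adjusted p = 9.1e-15; 9 of 15, 12 adjusted over the list alone) and the MHC class II list -0.54 (adjusted p = 1.02e-08; 5 of 7, 6 adjusted over the list alone), both with adjusted p = 0.0963 with an estimated correlation. MHC class I had -0.44 (adjusted p = 2.36e-07; 5 of 10, 6 adjusted over the list alone) and adjusted p = 0.313 with an estimated correlation. The cytotoxic list had -0.46 (adjusted p = 0.000533; 1 of 14, 5 adjusted over the list alone) and adjusted p = 0.467 with an estimated correlation. Epidermal differentiation had 0.28 (adjusted p = 7.24e-05; 4 adjusted over the list alone) and adjusted p = 0.44 with an estimated correlation, and cell cycle 0.32 (adjusted p = 0.00558) and adjusted p = 0.65 with an estimated correlation. The T cell list did not pass at -0.27 (adjusted p = 0.0539), nor did the interferon gamma response at -0.26 (adjusted p = 0.303).

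The week 6 comparison of jak12i with PBS gavage asks the same of the inhibitor given as jak12i. Clock genes moved in both directions: Per2, Per3 and the output gene Dbp of the same rhythm rose, while Arntl, Clock and Npas2 of the opposite arm were called lower. Antigen presentation genes fell, among them H2-DMa and H2-Ob of peptide loading on class II, Cd74 and the immunoproteasome gene Psmb9. Genes of dividing cells such as Aspm, Ccnb2 and Mki67 fell, as did the cytokine signalling genes Jak2 and Stat3. Limma called 203 genes higher and 1105 lower (n = 5 and 5). The share called higher was 15.5% as deposited and 42.6% after quantile normalization. Arrays of both groups did not overlap for 1105 genes, 8.10%, where chance gives 0.794%. The count of 1308 became 773 and 848 without PBS gavage replicates 3 and 5, and 3975 against PBS pump in place of PBS gavage. PBS gavage replicate 5 also had the lowest skeletal muscle list of its group, 7.46 against 12.2 to 13.3.

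Per2 rose by 1.95 ± 0.26 under jak12i at week 6, 3.88-fold (adjusted p = 7.11e-06; 7.96 ± 0.45 against 6.00 ± 0.15), Per3 by 1.91 ± 0.32 (adjusted p = 0.000146) and Dbp by 1.66 ± 0.43 (adjusted p = 0.00971). Arntl, Clock and Npas2, added here after their values were seen, changed by -1.16, -0.70 and -1.06 (adjusted p = 0.000113, 4.93e-05 and 0.00479). The stress response gene Chac1 rose by 2.27 ± 0.44 (4.83-fold, adjusted p = 0.000734), and the neutrophil gene S100a9 by 1.10 ± 0.27 with overlapping groups (adjusted p = 0.00798). Rsf1 and Itsn2 changed by -1.38 ± 0.14 and -1.71 ± 0.21 (adjusted p = 1.13e-07 and 2.26e-06), with other probe sets up to 0.06 and -0.09. H2-DMa, H2-Ob and Cd74 changed by -0.88, -1.21 and -0.66 (adjusted p = 9.99e-05, 2.11e-05 and 0.000447), and Psmb9, with overlapping groups, by -0.88 ± 0.20 (adjusted p = 0.00326). Iigp1 changed by -1.94 ± 0.57 (adjusted p = 0.0241). Cd3g and Nkg7 changed by -0.96 ± 0.20 and -0.88 ± 0.23 (adjusted p = 0.00152 and 0.00986). Aspm, Ccnb2 and Mki67 changed by -1.40, -1.23 and -0.92 (adjusted p = 0.00036, 0.00122 and 0.0181), and the groups overlapped for Mki67. Other Aspm probe sets reached 0.07. Jak2 and Stat3 changed by -0.36 ± 0.06 and -0.43 ± 0.09 (adjusted p = 0.000223 and 0.00101). Cd8a, Cxcl9 and the hair keratin gene Krt31 did not pass at -0.08 ± 0.15, -1.64 ± 0.57 and 1.72 ± 0.86 (adjusted p = 0.786, 0.0601 and 0.203).

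By camera 14 lists differed under jak12i at week 6, and with an estimated correlation none did, their smallest adjusted p being 0.279. MHC class II had a mean of -0.53 (adjusted p = 4.95e-07; 6 of 7 members fell over all genes, 7 adjusted over the list alone) and MHC class I -0.48 (adjusted p = 3.44e-06; 7 of 10, 9 adjusted over the list alone). The interferon gamma list had -0.77 (adjusted p = 0.000484; 4 of 18, 11 adjusted over the list alone), the cytotoxic list -0.39 (adjusted p = 0.0254; 3 of 14, 3 adjusted over the list alone) and the type I interferon list -0.39 (adjusted p = 0.0191; 4 of 19, 6 adjusted over the list alone). Without PBS gavage replicate 5 these 3 lists had -0.43, -0.25 and -0.25, and none of them passed. The common gamma chain and JAK-STAT list had -0.23 (adjusted p = 0.00136; 4 of 18). Hair shaft genes were higher by 1.44 (adjusted p = 4.95e-07) and inner root sheath genes by 1.39 (adjusted p = 0.000768), as 2 jak12i arrays, replicates 2 and 3, had hair shaft list means above 9. Without those replicates and sham replicate 4 the hair shaft difference was -0.0663. The skeletal muscle list was higher by 1.43 (adjusted p = 2.92e-05), where PBS gavage replicate 5 was the low array, and by 0.347 without it. Cell cycle genes had -0.48 (adjusted p = 0.0176; 4 of 13, 7 adjusted over the list alone), and without that array -0.286, which did not pass. Macrophage, dendritic cell and dermal matrix lists were lower (-0.40, -0.33 and -0.43; adjusted p = 0.0257, 0.0268 and 0.0257) and stressed epidermis higher (0.34; adjusted p = 0.0434). The last reversed to -0.267 without the arrays with high hair keratins and to -0.150 with the hair shaft list mean as a covariate.

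The difference of the 2 JAK inhibitor effects at week 6, jak3i minus jak12i, asks whether the inhibitors acted alike early. Genes of dividing cells and Il1rn stood higher under jak3i, while Per2, Per3 and Chac1 stood higher under jak12i. Limma called 212 genes higher and 111 lower. Aspm differed by 1.94 ± 0.39 (adjusted p = 0.00866), Il1rn by 1.55 ± 0.27 (adjusted p = 0.00295), Per2 by -1.78 ± 0.40 (adjusted p = 0.0157), Chac1 by -2.88 ± 0.67 (adjusted p = 0.0177) and the glutathione transferase gene Gstt2 by -1.77 ± 0.29 (adjusted p = 0.00291). The type I interferon list stood lower under jak3i by a mean of -0.63 (adjusted p = 1.18e-05) and adjusted p = 0.743 with an estimated correlation. The macrophage list had -0.68 (adjusted p = 4.47e-05) and cell cycle genes 0.80 (adjusted p = 7.55e-05), both with adjusted p = 0.743 with an estimated correlation. The share called higher was 65.6% as deposited and 54.5% after quantile normalization. The count of 323 became 196 without jak12i replicate 2, 859, 85 and 13 without PBS pump replicates 1, 2 and 3, and 121 without PBS gavage replicate 3. Different routes of the PBS controls entered this difference, and with the routes exchanged 6576 genes were called.

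The 3 week 13 comparisons ask what each treatment changed when disease had time to develop in the PBS groups. In every one of them the genes of cytotoxic T cells fell: the coreceptor gene Cd8a, the killing enzymes Gzma and Gzmb, and Ifng. Cxcl9 and Cxcl10, chemokines that interferon gamma induces and that draw T cells, fell too, and so did the machinery that loads peptides on MHC class I. Of the fat cell list, 4 of 8 genes rose in every comparison, among them Adipoq, which encodes adiponectin, but with an estimated correlation the list passed under il15rb only. The plot of immune list means shows the PBS groups of week 13 above all other groups for the cytotoxic list.

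**Figure D2:**
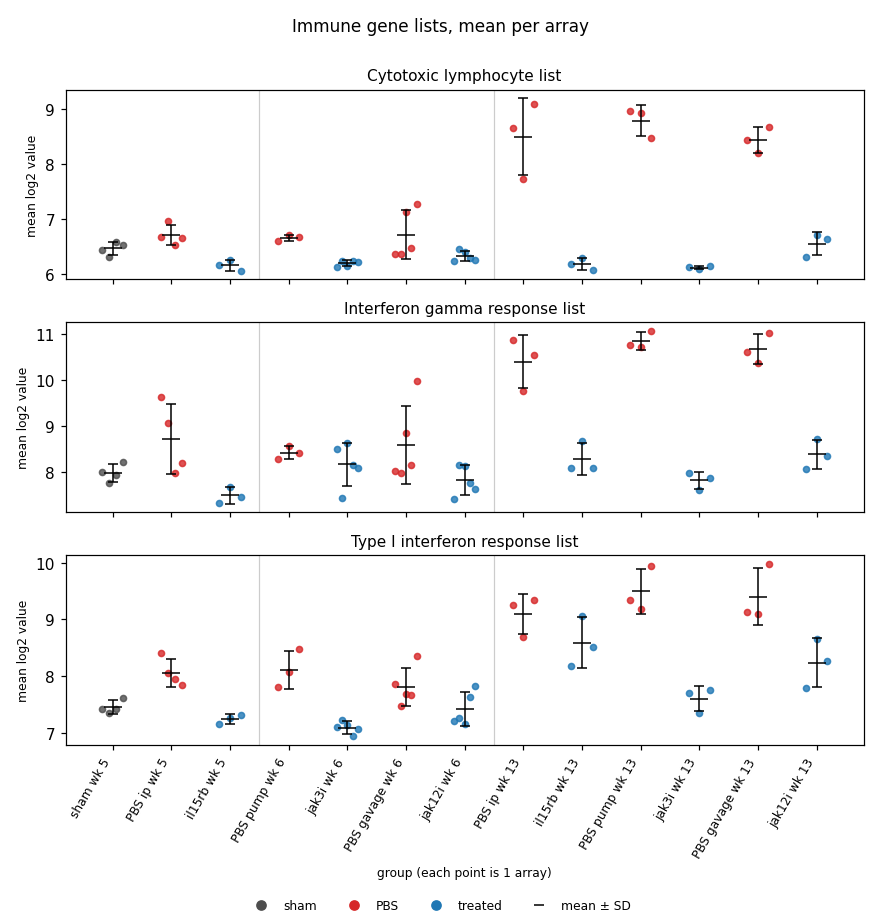
Mean log2 signal of the cytotoxic lymphocyte, interferon gamma response and type I interferon lists for every array in 13 groups, with each group's mean and SD. In the cytotoxic list the 9 PBS arrays of week 13 lie between 7.73 and 9.10, and the 9 treated arrays of that week between 6.07 and 6.70.

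Under il15rb at week 13, limma called 2059 genes higher and 1453 lower (n = 3 and 3), of which 538 and 272 changed at least 2-fold. Groups did not overlap for 5019 genes, 36.8%, where chance gives 10%. Cd8a fell by 2.17 ± 0.20, 4.49-fold (adjusted p = 4.06e-09; 6.89 ± 0.27 against 9.06 ± 0.52). Gzma fell by 4.89 ± 0.46, at least 29.8-fold, and the ubiquitin-like gene Ubd by 5.49 ± 0.53, at least 45.1-fold (adjusted p = 4.06e-09 and 5.58e-09). Gzmb, Ifng and Cxcl9 changed by -3.45 ± 0.40, -1.89 ± 0.26 and -4.39 ± 0.74 (adjusted p = 1.81e-07, 2.09e-06 and 4.03e-05). The gene of the blocked receptor chain, Il2rb, changed by -1.55 ± 0.15 (2.92-fold lower, adjusted p = 4.06e-09), while Il15 did not pass at 0.22 ± 0.17 (adjusted p = 0.373). H2-K1, the class I heavy chain, changed by -1.33 ± 0.17 (adjusted p = 7.02e-07), and the checkpoint genes Pdcd1 and Cd274 by -1.04 ± 0.21 and -1.40 ± 0.32 (adjusted p = 0.000382 and 0.00131). Keratins of injured epidermis, Krt16 and Krt17, changed by -2.82 ± 0.62 and -1.32 ± 0.23 (adjusted p = 0.000958 and 8.34e-05). Adipoq rose by 2.297 ± 0.27, 4.91-fold (adjusted p = 1.8e-07), the regulator of fat cell formation Pparg by 1.60 ± 0.20 (adjusted p = 7.37e-07) and the bulge stem cell keratin Krt15 by 0.75 ± 0.19 (adjusted p = 0.00331). Muscle genes led the rises: myosin gene Myh2 rose by 3.996 ± 1.13 (adjusted p = 0.0085; 12.50 ± 0.27 against 8.51 ± 3.04). The count of 3512 became 2205 without il15rb replicate 3, and 2034 and 1812 without PBS ip replicates 1 and 3. With the skeletal muscle and adipocyte list means as covariates, 49 genes passed.

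By camera at week 13 the cytotoxic list was lower under il15rb by a mean of -2.32 (adjusted p = 2.23e-22; 14 of 14 members fell over all genes and 14 adjusted over the list alone) and the T cell list by -0.94 (adjusted p = 1.01e-10; 11 of 11 and 11 adjusted over the list alone), both with adjusted p = 0.00541 with an estimated correlation. The checkpoint list had -0.999 (adjusted p = 0.000114; 4 of 5) and adjusted p = 0.0101 with an estimated correlation. The interferon gamma list had -2.10 (adjusted p = 8.56e-13; 17 of 18 and 17 adjusted over the list alone) and adjusted p = 0.0823 with an estimated correlation. MHC class I had -1.02 (adjusted p = 1.03e-11; 10 of 10) and adjusted p = 0.0647 with an estimated correlation, and MHC class II -0.42 (adjusted p = 0.00186; 5 of 7) and adjusted p = 0.309 with an estimated correlation. The type I interferon list had -0.51 (adjusted p = 0.00149; 8 of 19) and adjusted p = 0.506 with an estimated correlation, and without il15rb replicate 1 it had -0.31 and no longer passed. Stressed epidermis had -1.84 (adjusted p = 5.61e-06; 8 of 12, 11 adjusted over the list alone) and adjusted p = 0.127 with an estimated correlation. The adipocyte list was higher by 1.67 (adjusted p = 4.67e-11; 8 of 8) and adjusted p = 0.0261 with an estimated correlation. Skeletal muscle was higher by 3.18 (adjusted p = 8.3e-06; 14 of 15) and adjusted p = 0.42 with an estimated correlation, and PBS ip arrays ranged from 7.15 to 12.5 in this list. Without PBS ip replicate 3 it was higher by 1.765. Hair shaft genes had -1.71 (adjusted p = 0.000842; 0 of 22 called) and adjusted p = 0.507 with an estimated correlation, and the mean reversed to 0.137 with the muscle and adipocyte covariates. Bulge and germ genes had 0.52 (7 rose and 1 fell), sebaceous genes 0.82 (5 rose and 1 fell) and cell cycle genes -0.47 (adjusted p = 0.0192, 0.00497 and 0.0178). With an estimated correlation they had adjusted p = 0.42, 0.127 and 0.507, and cell cycle genes reversed to 0.0318 with these covariates.

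**Figure D3:**
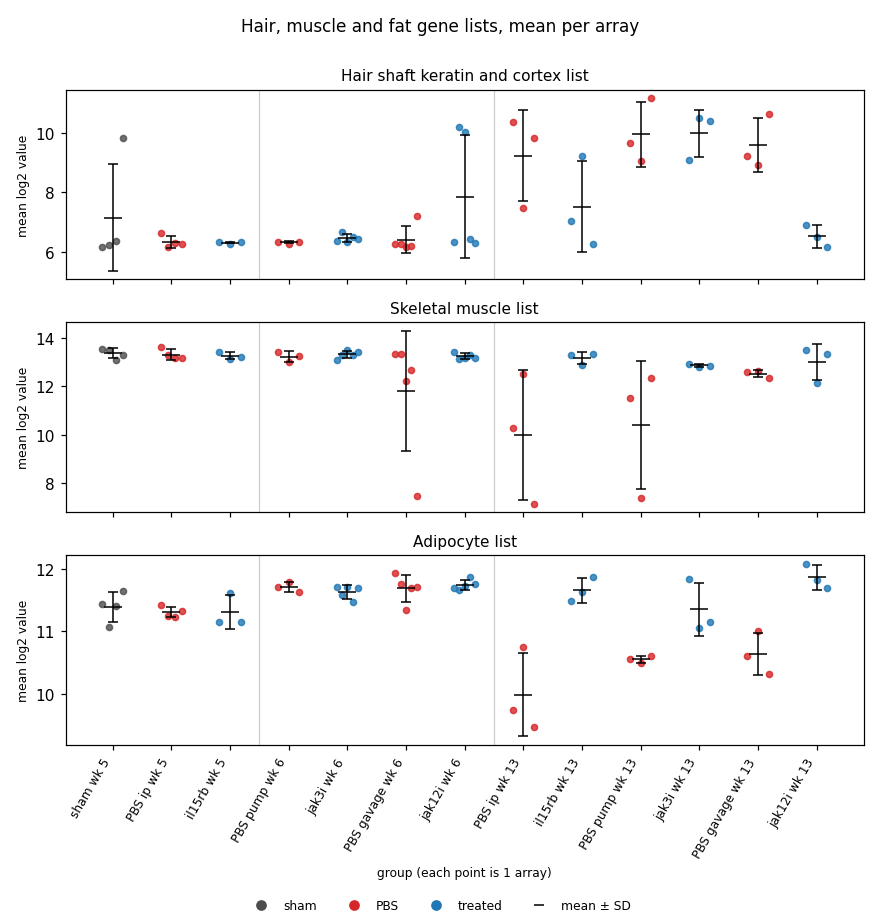
Mean log2 signal of the hair shaft, skeletal muscle and adipocyte lists for every array in 13 groups, with each group's mean and SD. One PBS ip and 1 PBS pump array of week 13 and 1 PBS gavage array of week 6 lie below 8 in the muscle list, and the adipocyte list of the PBS groups of week 13 averages between 9.99 and 10.6.

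Under jak3i at week 13, limma called 1319 genes higher and 863 lower (n = 3 and 3), 277 and 260 of them at least 2-fold. Groups did not overlap for 4056 genes, 29.7%, where chance gives 10%. Ubd fell by 6.17 ± 0.53, at least 71.9-fold (adjusted p = 2.09e-10), Gzma by 5.61 ± 0.46, at least 48.7-fold (adjusted p = 1.2e-10), and Cxcl9 by 5.45 ± 0.74, 43.6-fold (adjusted p = 1.25e-06). Cd8a fell by 2.40 ± 0.20, 5.28-fold (adjusted p = 1.2e-10; 6.71 ± 0.01 against 9.10 ± 0.19). Gzmb, Ifng and Il2rb changed by -4.67 ± 0.40, -2.07 ± 0.26 and -1.59 ± 0.15 (adjusted p = 2.09e-10, 3.05e-07 and 7.76e-10). The antiviral gene Oasl2 fell by 3.48 ± 0.43, 11.1-fold (adjusted p = 2.19e-07), and the peptide transporter gene Tap2 and the class II master regulator Ciita changed by -1.60 ± 0.16 and -1.12 ± 0.13 (adjusted p = 6.94e-09 and 1.63e-07). Il15ra changed by -0.48 ± 0.11 (adjusted p = 0.00252), while Il15 did not pass at -0.05 ± 0.17 (adjusted p = 0.894). Rises included the anion exchanger gene Slc26a7 at 2.48 ± 0.45 (adjusted p = 0.000139), the keratin gene Krt24 at 2.21 ± 0.34 (adjusted p = 1.06e-05), Cthrc1 of collagen matrix at 2.23 ± 0.46 (adjusted p = 0.000719), Lum at 1.09 ± 0.26 (adjusted p = 0.00311) and Adipoq at 1.29 ± 0.27 (adjusted p = 0.000761). Krt31 did not pass at 0.38 ± 1.11 (adjusted p = 0.865). The count of 2182 became 1451 and 1399 without jak3i replicates 1 and 3, and with the skeletal muscle and adipocyte list means as covariates 519 passed.

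By camera at week 13 the cytotoxic list stood at a mean of -2.67 under jak3i (adjusted p = 7.55e-34; 14 of 14 members fell), the interferon gamma list at -3.01 (adjusted p = 1.41e-29; 17 of 18, 18 adjusted over the list alone), the type I interferon list at -1.89 (adjusted p = 2.12e-28; 19 of 19) and the MHC class I list at -1.45 (adjusted p = 4.99e-24; 10 of 10). With an estimated correlation these had adjusted p = 0.000207, 0.00315, 0.00672 and 0.00315. The T cell, checkpoint, MHC class II and common gamma chain lists stood at -0.98, -1.35, -0.72 and -0.45 (adjusted p = 6.86e-13, 1.91e-08, 2.19e-08 and 1.92e-06; 9 of 11, 5 of 5, 6 of 7 and 10 of 18), with adjusted p = 0.00112, 0.000207, 0.0236 and 0.0107 with an estimated correlation. Stressed epidermis had -1.45 (adjusted p = 1.52e-05; 4 of 12, 8 adjusted over the list alone) and adjusted p = 0.134 with an estimated correlation. Dermal matrix was higher by 0.80 (adjusted p = 0.000244; 4 of 10, 10 adjusted over the list alone) and adjusted p = 0.262 with an estimated correlation. The adipocyte list had 0.80 (adjusted p = 0.000174; 4 of 8) and adjusted p = 0.174 with an estimated correlation, and skeletal muscle 2.44 (adjusted p = 0.000212; 1 of 15, 11 adjusted over the list alone) and adjusted p = 0.382 with an estimated correlation. Without PBS pump replicate 2 the muscle list had 0.934 and no longer passed. The muscle gene Myh4 rose by 3.58 ± 1.27 with overlapping groups (adjusted p = 0.0494). Hair shaft genes did not differ past the threshold at 0.02 (adjusted p = 0.654). Smaller list shifts were those of regulatory T cell (-0.57), macrophage (-0.37), dendritic cell (-0.33), cell cycle (-0.47), epidermal differentiation (-0.26) and bulge genes (0.45), with adjusted p from 0.00345 to 0.0473 and from 0.0655 to 0.554 with an estimated correlation. Without PBS pump replicate 1 the macrophage list had -0.07, and without PBS pump replicate 3 the cell cycle list had -0.163 and the bulge list 0.261, and none of these passed.

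Under jak12i at week 13, limma called 1580 genes higher and 1407 lower (n = 3 and 3), 228 and 383 of them at least 2-fold. Groups did not overlap for 5052 genes, 37.0%, where chance gives 10%. Besides the cytotoxic genes, genes of the hair shaft fell, among them Krtap4-16, a keratin-associated protein gene, and Krt31, though their list did not pass with an estimated correlation (adjusted p = 0.221). Cd8a fell by 1.88 ± 0.20, 3.68-fold (adjusted p = 5.66e-08; 7.12 ± 0.26 against 8.998 ± 0.33), Gzma fell by 4.35 ± 0.46, at least 20.4-fold (adjusted p = 5.66e-08), and Cxcl9 by 4.46 ± 0.74, 22-fold (adjusted p = 3.99e-05). Gzmb, Ifng, Ubd and Il2rb changed by -3.75 ± 0.40, -1.90 ± 0.26, -4.96 ± 0.53 and -1.14 ± 0.15 (adjusted p = 5.66e-08, 2.62e-06, 5.66e-08 and 1.24e-06). Krtap4-16 fell by 6.66 ± 1.59, at least 101-fold (adjusted p = 0.00256), and Krt31 by 3.64 ± 1.11, 12.5-fold (adjusted p = 0.0162; 6.28 ± 0.40 against 9.92 ± 1.16). The companion layer keratin Krt6b changed by -6.21 ± 1.19 (adjusted p = 0.000244), the cornified envelope gene Sprr2d by -3.13 ± 0.47 (adjusted p = 1.18e-05) and the mitotic kinase gene Cdk1 by -1.23 ± 0.30 (adjusted p = 0.00302). Rises included Krt24 at 3.00 ± 0.34 (adjusted p = 1.36e-07), the hair cycle growth factor gene Fgf18 at 2.79 ± 0.51 (adjusted p = 0.000132), Krt15 at 1.31 ± 0.19 (adjusted p = 5.57e-06), Adipoq at 2.15 ± 0.27 (adjusted p = 5.51e-07) and the milk casein gene Csn1s2a at 3.70 ± 0.84 (adjusted p = 0.00169). Pdcd1 and Il15 did not pass at -0.16 ± 0.21 and 0.15 ± 0.17 (adjusted p = 0.627 and 0.573). The count of 2987 became 1449 without PBS gavage replicate 3, and with the skeletal muscle and adipocyte list means as covariates 447 passed.

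By camera at week 13 the cytotoxic list had a mean of -1.89 under jak12i (adjusted p = 2.53e-17; 14 of 14 members fell) and adjusted p = 0.026 with an estimated correlation. The interferon gamma list had -2.28 (adjusted p = 1.31e-16; 18 of 18) and stressed epidermis -2.88 (adjusted p = 6.51e-11; 11 of 12), both with adjusted p = 0.0577 with an estimated correlation. MHC class I had -0.97 (adjusted p = 4.31e-12; 10 of 10) and adjusted p = 0.0602 with an estimated correlation. The type I interferon list had -1.17 (adjusted p = 2.25e-12; 14 of 19, 16 adjusted over the list alone) and the T cell list -0.49 (adjusted p = 0.000265; 7 of 11), both with adjusted p = 0.102 with an estimated correlation. MHC class II had -0.40 (adjusted p = 0.00174; 4 of 7) and adjusted p = 0.221 with an estimated correlation. Hair shaft genes had -3.07 (adjusted p = 1.76e-09; 16 of 22, 19 adjusted over the list alone) and cell cycle genes -0.95 (adjusted p = 1.08e-06; 11 of 13), both with adjusted p = 0.221 with an estimated correlation. Inner root sheath genes had -2.90 (adjusted p = 0.000714; 6 of 11) and adjusted p = 0.253 with an estimated correlation. The adipocyte list was higher by 1.22 (7 of 8) and bulge and germ genes by 0.80 (7 of 12), at adjusted p = 1.58e-07 and 0.000209, and 0.081 and 0.11 with an estimated correlation. Skeletal muscle did not pass at 0.47 (adjusted p = 0.582). Checkpoint, macrophage, neutrophil, epidermal differentiation and melanocyte lists stood at -0.77, -0.55, -0.57, -0.56 and -0.96, with adjusted p from 0.000265 to 0.0467 and from 0.0577 to 0.427 with an estimated correlation. Without PBS gavage replicate 2 the melanocyte list had -0.49 and no longer passed.

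Across the 3 treatments of week 13, 472 genes fell in every comparison, where 9.47 would be shared by independent calls, and 603 rose in every comparison, where 23.03 would be. Their control arrays were not shared. The falls in common held 14 of 14 cytotoxic genes, 10 of 10 MHC class I genes, 17 of 18 interferon gamma response genes, 7 of 11 T cell genes and 8 of 19 type I interferon genes. Averaged over the treatments, Ubd had -5.54, Gzma -4.95, Cxcl9 -4.77 and the chemokine gene Ccl5 -4.01. The rises in common held 5 of 12 bulge genes, 4 of 8 adipocyte genes and 2 of 8 sebaceous genes, with Slc26a7 at 2.68, Krt24 at 2.67, Pon1 at 2.46 and Adipoq at 1.91. Across genes, which are not independent replicates, the log2 changes of il15rb and jak3i had a Pearson r of 0.799, those of il15rb and jak12i 0.779, and those of jak3i and jak12i 0.644.

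The difference of the JAK inhibitor effects at week 13, jak3i minus jak12i, asks whether the inhibitors ended alike. The matrix gene Cthrc1 was the 1 gene called, and T cell lists stood lower under jak3i. Cthrc1 differed by 4.20 ± 0.65 (adjusted p = 0.00199), and 899 genes had an unadjusted p under 0.05. The cytolytic pore gene Prf1 differed by -1.18 ± 0.29 (adjusted p = 0.256) and Krt31 by 4.02 ± 1.57 (adjusted p = 0.642). The T cell list had -0.49 (adjusted p = 3.08e-07; 0 called over all genes, 5 adjusted over the list alone), the regulatory T cell list -0.69 (adjusted p = 9.83e-06) and the checkpoint list -0.58 (adjusted p = 0.000399), with adjusted p = 0.03, 0.0133 and 0.03 with an estimated correlation. The cytotoxic list had -0.78 (adjusted p = 6.86e-10; 5 adjusted over the list alone) and adjusted p = 0.0715 with an estimated correlation. Hair shaft genes stood higher under jak3i by 3.09 (adjusted p = 9.8e-15; 0 called over all genes, 11 adjusted over the list alone) and adjusted p = 0.132 with an estimated correlation, and dermal matrix genes by 1.06 (adjusted p = 9.84e-10; 9 adjusted over the list alone) and adjusted p = 0.0748 with an estimated correlation. The share called higher was 100% as deposited and 50% after quantile normalization. The count of 1 became 2 without jak3i replicate 2, 5 without jak12i replicate 1, 2 and 13 without PBS pump replicates 1 and 3, and 3 and 4 without PBS gavage replicates 1 and 3.

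The comparison of PBS week 13 with PBS weeks 5 and 6, each route with equal weight, asks what vehicle-treated skin expressed late against early. Hair shaft genes, cytotoxic and interferon genes and genes of injured epidermis stood higher late, and fat cell and muscle genes stood lower. None of these lists passed with an estimated correlation. Title week and this comparison cannot be told apart, because every late array also differs from every early array in its spread of values. Limma called 7181 genes higher and 3655 lower (n = 9 and 12). The median change of all genes was 0.18 as deposited, -0.02 after quantile normalization and 0.15 after subtracting array medians, and the share called higher was 66.3% as deposited and 48.1% after quantile normalization. Gzmb stood higher by 3.47 ± 0.22 (11.1-fold, adjusted p = 2.87e-16), Cxcl9 by 4.27 ± 0.40 (adjusted p = 6.14e-12), Cd8a by 0.84 ± 0.11 (adjusted p = 1.16e-08), Il15 by 0.51 ± 0.09 (adjusted p = 8.63e-06) and Il15ra by 0.66 ± 0.06 (adjusted p = 3.15e-12). The root sheath keratin gene Krt25 stood higher by 6.95 ± 1.04 (adjusted p = 1.96e-07) and Krt31 by 3.82 ± 0.60 (adjusted p = 5.49e-07). Iapp, which encodes amylin, stood lower at -3.603 ± 0.13 (adjusted p = 1.41e-22).

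By camera the late PBS arrays stood higher than the early ones in hair shaft by 3.23 (adjusted p = 0.0089; 21 of 22), stressed epidermis by 2.68 (adjusted p = 0.00609; 12 of 12), cytotoxic lymphocyte by 1.88 (adjusted p = 0.000297; 14 of 14), interferon gamma response by 2.05 (adjusted p = 0.00139; 18 of 18), type I interferon by 1.34 (adjusted p = 0.00112; 19 of 19), cell cycle by 1.44 (adjusted p = 0.00319; 13 of 13) and MHC class I genes by 0.81 (adjusted p = 0.0217; 9 of 10). Lower were adipocyte genes at -1.18 (adjusted p = 0.000109; 8 of 8), skeletal muscle at -1.80 (adjusted p = 0.00185; 15 of 15) and bulge genes at -0.41 (adjusted p = 0.0375; 6 of 12). With an estimated correlation none of these 10 lists passed, with adjusted p = 0.694 for 9 of them and 0.827 for hair shaft. The T cell list did not pass at 0.32 (adjusted p = 0.766).

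The last comparisons ask whether each treatment's effect at week 13 differed from its effect at week 5 or 6, within routes. By camera the fall of the cytotoxic list was larger late than early for every treatment, but for jak12i it did not pass with an estimated correlation (adjusted p = 0.0747). For il15rb 6 of 100 splits of the arrays, the real one included, gave as many genes as its difference between weeks. Those splits exchanged il15rb and PBS ip arrays within each week, so they cannot tell whether the effects of both weeks were equal. For il15rb, limma called 898 genes higher and 555 lower, for jak3i 842 and 411, and for jak12i 1445 and 759. The share called higher was 61.8%, 67.2% and 65.6% as deposited and 49.2%, 56.3% and 53.4% after quantile normalization. Cd8a differed by -2.24 ± 0.27 for il15rb, -2.31 ± 0.27 for jak3i and -1.80 ± 0.25 for jak12i (adjusted p = 6.79e-06, 1.52e-06 and 2.2e-05). Gzmb differed by -3.37 ± 0.55, -4.26 ± 0.54 and -3.45 ± 0.51 (adjusted p = 0.000184, 3.33e-06 and 3.32e-05). Cxcl9 did not pass for il15rb at -1.996 ± 1.01 (adjusted p = 0.194). Pgr differed by 3.83 ± 0.96 under il15rb, Ccn3 by 3.24 ± 0.59 under jak3i and Klb by 2.75 ± 0.34 under jak12i (adjusted p = 0.00938, 0.000588 and 6.7e-06). Krt31 differed by -5.36 ± 1.40 for jak12i (adjusted p = 0.00766).

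By camera the cytotoxic list's late effect minus its early effect was -1.77 for il15rb, -2.21 for jak3i and -1.50 for jak12i (adjusted p = 2.93e-13, 5.22e-24 and 4.12e-12; 11, 13 and 7 of 14 called), with adjusted p = 0.0364, 0.00208 and 0.0747 with an estimated correlation. The interferon gamma list had -0.88, -2.75 and -1.50 (adjusted p = 0.00103, 1.28e-23 and 1.04e-08), with adjusted p = 0.479, 0.0162 and 0.166 with an estimated correlation. The adipocyte list had 1.67, 0.87 and 1.17 (adjusted p = 1.21e-10, 0.000173 and 4.97e-05), with adjusted p = 0.0364, 0.194 and 0.166 with an estimated correlation. Hair shaft genes had -4.50 for jak12i (adjusted p = 7.16e-16; 19 of 22) and adjusted p = 0.166 with an estimated correlation. The count of 1453 for il15rb became 912 without il15rb week 5 replicate 2, 764 without il15rb week 13 replicate 3, and 717, 2622 and 624 without PBS ip week 13 replicates 1, 2 and 3. The count of 1253 for jak3i became 749 and 817 without PBS pump week 6 replicates 2 and 3, 660 without jak3i week 13 replicate 3 and 771 without PBS pump week 13 replicate 3. The count of 2204 for jak12i became 1091 without PBS gavage week 13 replicate 3.

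Genes called in PBS ip against sham at week 5 were followed as a list through the treatments. Of the 3 genes higher there, Per2, Sectm1b and Sectm1a, none was called under il15rb at week 5 and all had values below 0, with a median of -0.36 (camera adjusted p = 0.0264, and 0.122 with an estimated correlation). The PBS ip arrays enter both comparisons, and simulated data with no treatment effect gave a median of -0.23 by that sharing alone (95% range -0.50 to -0.083 over 100 simulations), so the median lay within what the shared control gives with no treatment effect. The same 3 genes had medians of -0.14 under jak3i at week 6 (adjusted p = 0.236), 0.26 under jak12i at week 6 (adjusted p = 0.0264, and 0.122 with an estimated correlation; Per2 alone was called), and -0.25, -0.12 and 0.32 under il15rb, jak3i and jak12i at week 13 (adjusted p = 0.995, 0.460 and 0.900). The 1 gene lower, Leo1, is too few for a list.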

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

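Tests on the immune, skeletal muscle and adipocyte lists were chosen only after their results were seen, while those on other splits of the arrays were not. The clock index was fixed before its own values were seen, but after those of other genes in the same arms, so it is no independent test.

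The cytotoxic lymphocyte and interferon gamma response lists fell under every treatment at week 13, though with an estimated correlation the interferon gamma list passed under jak3i only. Muscle and fat content of the biopsies as the whole cause is argued against: with the muscle and adipocyte list means as covariates, the cytotoxic list still fell, its weakest change being -1.27 ± 0.21 for il15rb (-2.32 without them), -5.933 SE from 0, and the interferon gamma list -1.56 ± 0.59 (-2.10 without them), -2.652 SE from 0. Hair follicle stage as the whole cause is argued against as well, since with the hair shaft list mean as a covariate the weakest changes were those of jak12i, -1.65 ± 0.24 or -6.945 SE for the cytotoxic list and -1.70 ± 0.40 or -4.211 SE for the interferon gamma list. Title week cannot part groups within week 13. Whether fewer T cells or less active ones lay behind the falls was not tested.

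Skeletal muscle and adipocyte lists stood higher under il15rb and jak3i at week 13, and the adipocyte list under jak12i too, but with an estimated correlation only the adipocyte list under il15rb passed. The members of the muscle list moved by a common amount, with an SD over members of 0.128 of the mean change for il15rb and 0.1707 for jak3i, consistent with less muscle under the skin in some PBS biopsies. Hair follicle stage stays open: within groups over 47 arrays, the hair shaft list and the muscle list had a Pearson r of -0.1442 (permutation p = 0.384, adjusted over 2 relations 0.384; Spearman rho -0.270, permutation p = 0.0931; r = -0.163 without the 2 farthest arrays). For the adipocyte list r was -0.2533 (permutation p = 0.187, adjusted 0.374; rho -0.247, permutation p = 0.150; r = -0.374 without the 2 farthest arrays). A loss of fat with the disease was not tested.

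Clock genes moved in jak12i against PBS gavage at week 6, and Per2 alone of them was called in PBS ip and in il15rb against sham at week 5, which a different time of day of collection may explain. An index of clock genes fixed before their values were seen, Per and Dbp arm minus Arntl arm, differed by 1.201 for jak12i (1.30 ± 0.31 against 0.10 ± 0.10, n = 5 and 5, exact permutation p = 0.00794, two-sided, 0.0635 adjusted over 8 comparisons) and by 1.06 for PBS ip (1.20 ± 0.07 against 0.14 ± 0.21, n = 4 and 4, exact permutation p = 0.0286, adjusted 0.0762). Handling stress through glucocorticoids, read from a list of their target genes, also had the values it needs in PBS ip against sham, 0.3598 (11.08 ± 0.09 against 10.72 ± 0.06, exact permutation p = 0.0286, adjusted 0.0762), and was left open for jak12i at 0.1944 (exact permutation p = 0.230, adjusted 0.307). In il15rb against PBS ip at week 5 the clock index differed by 0.0490 (exact permutation p = 0.571) and the glucocorticoid list by 0.482 (exact permutation p = 0.0286, adjusted 0.0762). In il15rb against sham they differed by 1.11 and 0.841 (each exact permutation p = 0.0286, adjusted 0.0762). Under il15rb at week 13 Per2, Tef, Nr1d2 and Clock of both arms were called higher, and Tef and Nr1d2 under jak3i, where the index differed by 0.229 and 0.458 (exact permutation p = 0.5 and 0.7). An action of jak12i on the clock stays open, as collection times are not in the labels.

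Single arrays stood far from their group in 6 of 55 group and list pairs tested, where chance gives about 1 in 20. Replicate 5 of PBS gavage week 6 accounted for 3: its skeletal muscle list was 7.463 (others 12.2 to 13.3), its hair shaft list 7.20 (others 6.17 to 6.27) and its stressed epidermis list 9.017 (others 7.61 to 7.93). It also had the highest cytotoxic and interferon gamma lists of its group, 7.26 and 9.97. Sham replicate 4 had a hair shaft list of 9.83 (others 6.18 to 6.38), jak3i week 6 replicate 4 a macrophage list of 8.171 (others 8.80 to 9.01) and jak12i week 6 replicate 1 an MHC class II list of 9.624 (others 9.82 to 9.86).

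The effect of a treatment differed between weeks for 1453 genes under il15rb, 1253 under jak3i and 2204 under jak12i, and the JAK inhibitor effects differed from each other for 323 genes at week 6 and for 1 gene at week 13, by limma tests of the differences. Other splits of the same arrays were counted for each result. The real grouping gave the most genes for jak12i at week 6 (1308 genes; 1 of 100 splits gave as many, highest other 309) and PBS late against early (10836; 1 of 100, highest other 7276). It also did for il15rb against sham (4; 1 of 35), but there the highest other was 3. Another split gave more genes than the real one for jak3i at week 6 (559; 2 of 56, highest other 623) and the JAK difference of week 6 (323; 2 of 100, highest other 732). The same held for the week differences of jak3i (1253; 2 of 100, highest other 1390) and jak12i (2204; 2 of 100, highest other 2516). In all of these the share was under 0.05, unadjusted over the results tried, so chance is less likely but not excluded. The share was above 0.05, and chance stays open, for PBS ip against sham (4; 2 of 35, highest other 19), il15rb against PBS ip at week 5 (10; 2 of 35, highest other 23), the week difference of il15rb (1453; 6 of 100, highest other 2206) and the JAK difference of week 13 (1; 47 of 100, highest other 2592). The 10 splits of each week 13 comparison are too few for a share under 0.05: il15rb had 3512 genes (highest other 1566), jak3i 2182 (79) and jak12i 2987 (66), each 1 of 10.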

How the results depend on the processing

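The hair shaft covariate, leaving out the low-muscle arrays, leaving out the arrays with high hair keratins and the list at an unadjusted p under 0.01 were chosen only after the data were seen. Of 290 named gene results that passed in the 8 comparisons of groups within a week, 196 passed with each array left out in turn, 270 after quantile normalization, 287 of 290 after subtracting array medians and 262 of 280 with the mean of a gene's probe sets, and none reversed. Of 87 list results that passed in 7 of these, without il15rb against sham, 60 passed with each array left out, 84 with a replicate block, 17 with an estimated correlation and 53 by fry. With covariates or other arrays, 66 of 81 kept their side and direction with the muscle and adipocyte covariates (2 reversed), 78 of 83 with the hair shaft covariate (3 reversed), 66 of 80 with all PBS arrays (4 reversed), 38 of 46 without the low-muscle arrays (0 reversed) and 14 of 21 without the arrays with high hair keratins (4 reversed). Array signals near background cannot show small changes, and genes never above the table's median in 3 arrays were not tested. List results of late against early PBS, of the week differences and of the JAK differences were not carried through these settings. Where no cause is named, the cause was not tested.

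Without the filter on dim probe sets the counts of genes were 2 for PBS ip against sham, 7 for il15rb against sham and 4 for the JAK difference of week 13. Quantile normalization gave 0, 6 for il15rb at week 5 and 2 for the JAK difference of week 13, and subtracting array medians gave 9 for il15rb against sham. Every probe set with 1 symbol gave 2337 for jak12i at week 6 and 526 and 6 for the JAK differences of weeks 6 and 13, where more features were tested by construction. The mean of a gene's probe sets gave 7 for il15rb against sham and 210 and 3 for the JAK differences.

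Fitting only the groups compared, with fewer arrays for the spread by construction, gave 20 genes for PBS ip against sham, 39 for il15rb at week 5, 296 for jak3i and 564 for jak12i at week 6, 816, 496 and 1907 for il15rb, jak3i and jak12i at week 13, 7 for il15rb against sham, 789 for the week difference of jak3i, and 32 and 0 for the JAK differences. Array weights gave 129, 469, 1663 for jak3i at week 6, 6352 and 3687 for il15rb and jak3i at week 13, 357 for il15rb against sham, 5211, 2330 and 3616 for the week differences, and 1105 and 121 for the JAK differences. Asking for at least a 2-fold change, stricter by construction, gave 1 for PBS ip against sham, 102 and 58 at week 6, 810, 537 and 611 at week 13, 2 for il15rb against sham, 1385 for PBS late against early, 585, 517 and 596 for the week differences and 46 for the JAK difference of week 6.

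A replicate block, which the labels do not call for, gave 2 genes each for PBS ip against sham, il15rb against PBS ip and il15rb against sham at week 5, and reversed the hair shaft list of il15rb at week 5 to 0.0423, a list that had not passed. The conflicting array taken as its title says gave 1 gene for il15rb at week 5, and as its treatment label says 24 there and 39 for il15rb against sham.

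With muscle and adipocyte covariates the counts were 7, 25, 49, 519 and 447 for PBS ip against sham, il15rb at week 5 and il15rb, jak3i and jak12i at week 13, 38 for il15rb against sham, 7194 for PBS late against early, and 12, 291 and 292 for the week differences. List shifts numbered 8 for jak12i at week 6 and 9 for il15rb at week 13, the list of genes higher in PBS ip than sham had medians of 0.0353 for jak3i and -0.558 for jak12i at week 13, and for il15rb at week 13 the hair shaft list became 0.137 and the cell cycle list 0.0318. With the hair shaft covariate the counts were 2, 16, 2339 and 856 for PBS ip against sham, il15rb at week 5 and il15rb and jak12i at week 13, 7 for il15rb against sham, 940 and 222 for the week differences of il15rb and jak12i, and 2 for the JAK difference of week 13. The median of the same list for jak12i at week 13 became -0.00899, the inner root sheath list of jak12i -0.0939 at week 6 and 0.273 at week 13, and its stressed epidermis list -0.150 at week 6.

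Leaving out the low-muscle arrays gave 860 genes for jak12i at week 6, 2186 for il15rb at week 13 and 844 for its week difference, 9 list shifts for jak12i at week 6, and for jak3i at week 13 a median of 0.163 in the PBS ip list and -0.434 in the hair shaft list. Leaving out the arrays with high hair keratins gave 2 for PBS ip against sham, 708 for jak12i at week 6, 1 for il15rb against sham, 1228 for the week difference of jak12i and 138 for the JAK difference of week 6, with 9 list shifts for jak12i at week 6. The hair shaft list became 0.0801 for PBS ip against sham and -0.0663 for jak12i at week 6, where inner root sheath became -0.207 and stressed epidermis -0.267.

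With all PBS arrays as control, which mixes title weeks 5 and 6 by construction, the counts were 6061 for il15rb at week 5, 6970 and 3377 for jak3i and jak12i at week 6, 5274 for jak12i at week 13, 4805, 5421 and 4941 for the week differences, and 4518 and 179 for the JAK differences, with 8 list shifts for jak12i at week 6. The PBS ip list had medians of 0.561, -0.654, -0.153 and 0.0420 for il15rb at week 5, jak3i and jak12i at week 6 and il15rb at week 13. For il15rb at week 5 the common gamma chain list became 0.102 and the cell cycle list 0.178, and for jak3i at week 6 the cell cycle list became -0.143 and epidermal differentiation -0.0650. With PBS of the other route the counts were 6246 and 3975 for jak3i and jak12i at week 6, 4557 for jak12i at week 13, 4209 and 4719 for the week differences of jak3i and jak12i, and 6576 and 144 for the JAK differences.

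With an estimated correlation 0, 4, 0, 0, 4, 8 and 1 lists shifted, in the order PBS ip against sham, il15rb at week 5, jak3i and jak12i at week 6, and il15rb, jak3i and jak12i at week 13, and by fry 0, 4, 4 and 4 for the first 4 of these. By fry the PBS ip list no longer passed for il15rb at week 5 at -0.359, and passed for jak3i at week 6 at -0.144. As the wider list its medians were -0.123 and 0.0265 for jak3i and jak12i at week 6 and 0.0182 and 0.0113 for il15rb and jak3i at week 13.

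Leaving out each array in turn gave from 0 to 3 genes for PBS ip against sham, 0 to 14 for il15rb at week 5, 165 to 895 and 773 to 1414 for jak3i and jak12i at week 6, 1812 to 4377, 1399 to 1999 and 1449 to 2846 for il15rb, jak3i and jak12i at week 13, 0 to 47 for il15rb against sham, 10608 to 10871 for PBS late against early, 624 to 2622, 660 to 1441 and 1091 to 2427 for the week differences, and 13 to 859 and 1 to 13 for the JAK differences. Arrays that moved a count by over 1.5 times are named with it in the results. List shifts ranged over 6 to 12, 8 to 11, 7 to 9, 7 to 14, 11 to 15, 16 to 18 and 17 to 18 in the order above. The PBS ip list had medians of -0.471 to -0.212 for il15rb at week 5, -0.188 to -0.106 for jak3i and 0.221 to 0.330 for jak12i at week 6, and -0.478 to -0.0530, -0.386 to 0.163 and -0.124 to 0.436 for il15rb, jak3i and jak12i at week 13. With arrays left out the sign reversed in the hair shaft list of PBS ip against sham (-1.136 without sham replicate 1 to 0.0801 without sham replicate 4), that of il15rb at week 5 (-0.092 without PBS ip replicate 3 to 0.0648 without PBS ip replicate 2), its cell cycle list (-0.470 without il15rb replicate 3 to 0.119 without il15rb replicate 1) and the hair shaft list of jak3i at week 13 (-0.434 without PBS pump replicate 2 to 0.624 without PBS pump replicate 3, and below 0 without each of 4 arrays). Of these, the hair shaft lists of il15rb at week 5 and jak3i at week 13 had not passed.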

Other observations

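The test of the type I interferon list between agents, the simulation of the shared control and the wider list were chosen only after the results were seen. At week 13 the 3 agents shared the rise of some bulge and sebaceous genes. Under jak3i the hair shaft list stood at 9.98 ± 0.78 (n = 3), near PBS pump at 9.95 ± 1.09, while under jak12i it stood at 6.52 ± 0.38 against 9.59 ± 0.90 and under il15rb at 7.52 ± 1.52 against 9.23 ± 1.53, overlapping both. The list's difference between the JAK inhibitors did not pass with an estimated correlation (adjusted p = 0.132). The early groups other than sham and jak12i averaged between 6.31 and 6.46. The growth factor gene Fgf18 of the resting follicle rose by 2.79 ± 0.51 under jak12i, by 1.94 ± 0.51 under il15rb, and by 1.69 ± 0.51 under jak3i, where the groups overlapped (limma adjusted p = 0.000132, 0.00469 and 0.0191).

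Within the IL-15 pathway at week 13, the receptor chain gene Il2rb fell under all 3 agents, whereas Il15 passed under none of them and Il15ra fell under jak3i, where the effects of jak3i and jak12i did not differ past the threshold (-0.39 ± 0.16, limma adjusted p = 0.648).

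A hypothesis was that JAK inhibition may reach the type I interferon receptor while IL-15 receptor blockade does not. The mean of the JAK inhibitor effects minus the il15rb effect at week 13 was -1.017 in the type I interferon list (camera adjusted p = 2.37e-22 over 25 lists), but adjusted p = 0.107 with an estimated correlation, so the criterion that asked for both was not met. The criterion was made stricter after its p-values had been seen. The interferon gamma list differed by -0.55 (adjusted p = 0.00027, and 0.482 with an estimated correlation) and the cytotoxic list by 0.04 (adjusted p = 0.703). In all, 10 lists besides the type I interferon list passed, from skeletal muscle at -1.72 to T cell genes at 0.20, none with an estimated correlation, so the difference was not confined to interferon genes. Limma called 1 gene higher and 0 lower in this difference.

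The array whose title and treatment label conflict had a T cell list of 7.22, where sham ranged from 7.57 to 7.85, PBS ip week 5 from 7.81 to 7.85 and il15rb week 5 from 7.37 to 7.46. Its cytotoxic list was 6.01 (sham 6.31 to 6.58, PBS ip 6.53 to 6.97, il15rb 6.06 to 6.25) and its interferon gamma list 7.50 (sham 7.77 to 8.22, PBS ip 7.99 to 9.62, il15rb 7.34 to 7.69). Nkg7 was 6.90, Cxcr6 5.80 and Per2 7.88 on it.

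With 96 genes higher in PBS ip than in sham at an unadjusted p under 0.01, the median under il15rb at week 5 was -0.0625 (camera adjusted p = 7.43e-12, and 0.0014 with an estimated correlation), and simulation of the shared control alone gave -0.157 (range -0.189 to -0.124). Under jak3i at week 6, whose control is not shared, it was -0.123 (adjusted p = 9.8e-07, and 0.0168 with an estimated correlation). For the 82 genes lower, the median was 0.0123 under il15rb at week 5 (camera adjusted p = 0.658), and 0.178 and 0.298 under il15rb and jak3i at week 13 with 63 of 82 above 0 in each (adjusted p = 0.000371 and 1.54e-05, each 0.439 with an estimated correlation). At week 6 they stood lower again under jak3i and jak12i, at -0.107 and -0.188 (adjusted p = 0.0128 and 0.000199, and 0.479 and 0.439 with an estimated correlation). Across genes, which are not independent replicates, the changes of both comparisons had r = -0.209 where the simulation gave -0.464.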
